A study of Mus musculus with 4 samples.

How the data were processed

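Droplet single-cell RNA counts were taken from 4 libraries of CD45+ cells sorted from Peyer's patches, 2 from mice without segmented filamentous bacteria (SFB-negative) and 2 from mice with them (SFB-positive). Per the labels, cells of 5 mice were pooled, 6000 cells were loaded per library and 4000 were targeted. The sources used here leave unclear whether replicates 1 and 2 of a group are separate pools of mice. The p-values therefore measure at most the spread between libraries, pooled in part across genes.

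The deposited matrices hold UMI counts, whole numbers without normalization, for 31053 genes and the barcodes with at least 500 gene UMIs. Per the submitters' processing notes, reads were processed with Cell Ranger 5.0.1 against mm10, whereas the counts carry Cell Ranger 6.0.0 for both replicate 1 libraries and 7.0.0 for both replicate 2 libraries, per the file headers. The intron setting and the annotation release are not given in the sources used here. The replicate 1 matrices hold counts of 15 antibody tags besides the genes, per the file headers. The authors also deposited a table of 22569 cells with a library code (other), a cluster number from 0 to 6, counts of UMIs and genes per cell, the percent of mitochondrial UMIs and UMAP layout coordinates (a score without unit). The deposited percent stayed under 10 in every table cell. The highest number of genes per table cell was 2980 and 2993 in the replicate 1 libraries, 3999 in SFB-negative replicate 2 and 5991 in SFB-positive replicate 2, so the limit on deep cells differed between libraries. The authors' cell filters, doublet removal and clustering settings are not given in the sources used here.

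Clusters 0 to 6 of the authors' table were used as they stand and named from marker genes fixed in advance. Clusters 0 and 1 were naive-like B cells (with Plaur, Ccr7 and Cd55, and with Hspa1a, Klf2 and Jun, among their leading genes), cluster 3 germinal-centre-like, cluster 4 memory-like, cluster 5 low-depth germinal-centre-like and cluster 6 plasma-like. Cluster 2 (Srm, Mir155hg, Myc) stayed unnamed. The table held B-lineage cells, so T cells were rebuilt from 6554 barcodes outside it with under 10% mitochondrial UMIs. These were clustered in 2 stages with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0, 22 clusters). After clusters with B-cell genes above 1000 CPM were set aside, 3848 cells were clustered again at resolution 1.2, giving 20 clusters. Of 14 clusters with at least 1000 CPM of Cd3 and T-cell receptor constant genes, 13 were used as the T lineage (2882 cells, an NK or ILC1-like cluster among them), and an epithelial-like cluster (2 and 99 cells in SFB-negative, 3 and 14 in SFB-positive libraries) was left out. That limit, that exclusion and a marker score minimum of 0.75 were set after the data were examined. The limit keeps the ILC3-like cells (type 3 innate lymphoid cells), 1.26% of annotated cells in SFB-negative and 0.550% in SFB-positive libraries, out of the T lineage. A name needed at least 3 detected markers. Naive CD4 T-like cells lay in different clusters by replicate number, so they were compared as 1 class. Because classes outside the table were rebuilt, their names can differ from the authors'.

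Counts were summed per library and class, and 9 classes with at least 20 cells in each library were compared. The test was the edgeR 4.0.16 quasi-likelihood test (robust, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment within a class, limit 0.05), in R 4.3.3. The model without the replicate number was chosen before the data were examined, with the replicate block (replicate number as a term) as an alternative. The replicate number turned out to mark a technical batch in the files: Cell Ranger version, antibody tags and depth differ by it. For that reason log2 differences and adjusted p-values are given from the model with the replicate block. In that model the spread of a gene is taken largely from all genes together. The median prior degrees of freedom were infinite in all B-lineage cells and cluster 3, and 36.8 in T-lineage cells. Very small adjusted p-values therefore do not measure the spread of that gene between the libraries of a group. The differences within each replicate number are given for some genes only, and the result without the block as counts and for the leading genes. In the text, "rose" and "fell" refer to the test with the replicate block unless another is named, and every adjusted p without another name comes from it. Log2 differences are SFB-positive minus SFB-negative.

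Both models were tested on simulated data drawn from the real means and depths, with 200 changed genes, a coefficient of variation of 0.15 and 3 draws. The means were those of each replicate number, and the spread was close to that fitted with the block. A shared replicate effect was thus built in, so the outcome favours the block by design. It does not show whether the real libraries share such an effect. Without the block, 0% of 8-fold changes were recovered in all B-lineage, cluster 3 and all T-lineage cells. With it, 100% of 4-fold and 8-fold changes were recovered in these classes, and 77.3%, 60.0% and 54.0% of 2-fold changes, at 7.00, 6.67 and 6.67 false calls among 12268, 9876 and 9371 genes.

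The genes named were fixed by a rule written before the data were examined: genes past the limit with at least 10 CPM in the higher group and the same sign within both replicate numbers, the 12 largest differences each way in all B-lineage, cluster 3 and all T-lineage cells and the 3 largest elsewhere, or the 10 smallest p-values where fewer than 5 genes passed. Some genes that the rule named are not reported here. Heavy-chain constant genes and up to 4 members of each of 26 gene lists were named always. After the data were examined, the rule was applied also to the model with the replicate block, among genes with at least 10 UMIs over the replicate 1 libraries. List members named beyond 4, antibody tags, and gene families were chosen after their values were seen. Variable segments, ribosomal, mitochondrial and unnamed gene models were counted as groups. Gene lists of at least 5 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), camera with an estimated correlation, and fry, with adjustment over lists. The effect in cluster 4 minus that in cluster 3 was tested with an interaction term in edgeR, with the library as a block, a test added after the data were examined. The same test of each of these clusters against cluster 0 was also run, and was left out after its values were seen.

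Shares of cells were tested with edgeR on the number of cells in 14 classes, beside an exact two-sided permutation test, whose smallest p with 2 against 2 libraries is 0.333. Isotype shares are percents of the UMIs of 8 heavy-chain constant genes per class and library. They were compared by the same exact test, with shares of cells by their dominant constant gene (at least 3 UMIs) beside them. Intervals of 95% (exact Clopper-Pearson for shares, exact Poisson-based for ratios) and floors of 3 counts cover counting error only. Gene positions came from GENCODE M21 (GRCm38, the mm10 build), in which 354 of 354 named genes were found by identifier.

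Alternatives tried were DESeq2 1.42.0, median-of-ratios scaling, no low-count filter, cells thinned to 1000 UMIs with shallower cells left out, immunoglobulin genes left out, high-scoring doublets left out, other denominators, T-cell background subtracted from isotype counts, and each library left out in turn. Doublets were kept in the main values. The Scrublet threshold marked too few cells, so the top 5% of scores per library (225, 561, 193 and 478 cells) formed the alternative, a choice made after the data were examined. Combinations with the replicate block, the wider germinal-centre share clusters 0 and 1 combined, and isotype shares without the cell with the most constant UMIs in each class and library were also added then. Barcodes with 10% or more mitochondrial UMIs (2762) and the unnamed cluster outside the table below the T-lineage limit were left out because no class could be given. The B-like barcodes set aside after the first clustering stage had names but were also left out of the annotated cells. The naive or follicular B-like clusters among them held 670, 812, 143, 132 and 13 barcodes in SFB-negative replicate 2. In SFB-positive replicate 2 the same clusters held 22, 34, 122, 237 and 0. Unnamed clusters above that limit stayed in the T lineage without a class of their own. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 were used.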

Results

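RNA was counted in single CD45+ (white blood) cells sorted from Peyer's patches, the lymphoid follicles of the small intestine. The female wild-type mice either lacked or carried segmented filamentous bacteria (SFB), gut commensals that attach to the ileal epithelium. Each group had 2 libraries. The comparison asks how SFB colonisation relates to antibody class switching to IgA and IgG2b and to memory B cells, the subjects named in the series title. SFB-negative replicates 1 and 2 held 7198366 and 47273320 UMIs over 4595 and 12921 barcodes, and SFB-positive replicates 1 and 2 held 6979187 and 83600989 UMIs over 4031 and 10338. Median UMIs per barcode were 1278 and 2875 against 1273 and 5786. The authors' table kept 4050, 7731, 3408 and 7380 cells of these libraries, all B lineage, and the T-lineage cells rebuilt from barcodes outside it numbered 290, 1046, 309 and 1237.

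Germinal-centre-like B cells (cluster 3), the dividing B cells in which antibody genes mutate and switch, carried a different mix of heavy-chain constant transcripts in the groups. Ighg1, the IgG1 heavy chain, took 39.3% ± 10.5 (SD, n = 2) of heavy-chain constant UMIs in SFB-negative and 9.51% ± 8.15 in SFB-positive libraries. Ighg2b, the IgG2b heavy chain, took 6.29% ± 2.33 and 26.8% ± 10.1, and Igha, the IgA heavy chain, 9.19% ± 1.45 and 29.5% ± 12.3. Ighm, the unswitched IgM heavy chain, took 41.5% ± 8.28 and 31.4% ± 5.86. Within replicate numbers 1 and 2 the Ighg1 share differed by -16.6 and -42.9 percentage points, that of Ighg2b by 26.0 and 15.0, and that of Igha by 10.6 and 30.1. The Ighm share differed by -20.1 points within number 1 and by -0.089 within number 2. In each of these 4 genes the groups did not overlap, and the exact two-sided permutation test gave p = 0.333, the smallest it can give with 2 against 2 libraries. Counting cells by their dominant constant gene, Ighg1 cells made up 51.8% and 6.78%, Igha cells 9.69% and 41.1%, and Ighg2b cells 7.10% and 27.6%. In SFB-positive replicate 1, 1 cell held 764 of the 1460 Ighg2b UMIs of cluster 3. With the cell of most constant UMIs left out of each library, Ighg2b took 6.23% and 20.4%, with differences of 12.2 and 16.2 points within the replicate numbers, Igha 9.60% and 29.4%, and Ighg1 41.2% and 11.3%, while the Ighm differences became -13.2 and 6.53 points. The 8-gene shares of Ighd (3.05% and 2.03%), Ighg3 (0.519% and 0.625%) and Ighe (0.184% and 0.0168%) were small. Ighg2c took 0% and 0.0691%, and its reads can be split with those of its near copy Ighg2b.

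**Figure D1:**
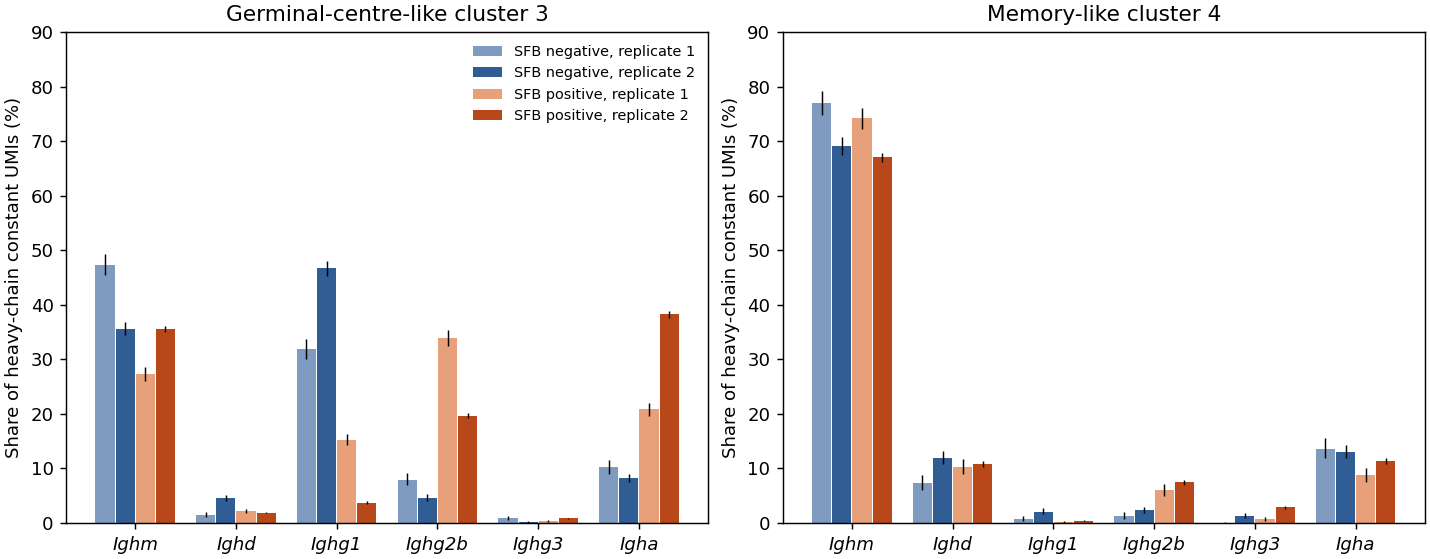
Share of the heavy-chain constant UMIs (percent, vertical axis) by gene in germinal-centre-like cluster 3 and memory-like cluster 4, with 1 bar per library and its exact 95% binomial interval, which covers counting error only. In cluster 3 Ighg2b and Igha stand higher and Ighg1 lower in both SFB-positive libraries than in both SFB-negative libraries.

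The same genes differed in level within cluster 3. Ighg2b rose by 2.64 ± 0.38 on the log2 scale (SE, n = 2 libraries per group, adjusted p = 2.05e-09), a 6.25-fold difference, from 291 and 48.8 CPM in SFB-negative to 1594 and 348 CPM in SFB-positive libraries. Igha rose 4.58-fold (log2 2.20 ± 0.37, adjusted p = 1.52e-06), and Ighg1 fell by 1.80 ± 0.39 on the log2 scale (adjusted p = 7.16e-04). Ighg3 (log2 1.30, adjusted p = 0.176), Ighm (0.16, 0.968) and Ighd (0.04, 0.992) did not pass. Without the replicate block none of these genes passed, and over the alternatives without it the adjusted p ranged from 0.183 to 1.00 for Ighg2b and stayed at 1.00 for Igha and Ighg1. Over these alternatives the log2 difference ranged from 1.07 to 4.27 for Ighg2b, from 1.15 to 3.21 for Igha and from -3.62 to -0.22 for Ighg1. Naive CD4 T-like cells, which should lack Ighg2b, held it at a lower rate than cluster 3 cells, by factors of 29.9 and 20.4 in SFB-positive replicates 1 and 2, or 14.4 and 20.1 without the cell of most Ighg2b UMIs in cluster 3 of each library. In CPM of the raw class totals, not scaled by TMM as above, leaving that cell out moved Ighg2b from 292 and 45.2 to 250 and 43.2 in SFB-negative and from 1541 and 382 to 741 and 377 in SFB-positive libraries. The antibody genes lie on the minus strand of chromosome 12 (GRCm38): Ighg2b (ENSMUSG00000076613) at 113302965 to 113307933, Igha (ENSMUSG00000095079) at 113254830 to 113260236, and Ighg1 (ENSMUSG00000076614) at 113325240 to 113330523.

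Further genes of cluster 3 separated the groups. Klrb1 (a lectin receptor gene, log2 1.79), Prr11 (a mitosis gene, 1.37), Id2 (an inhibitor of E-protein transcription factors, 1.72), Rsph1 (a radial spoke gene, 1.38) and Hspa1a (an inducible heat-shock chaperone, 1.87) rose. Fcer2a, which encodes the low-affinity IgE receptor CD23 of naive B cells, fell by 1.34 ± 0.30 on the log2 scale (adjusted p = 0.00169), from 208 and 122 CPM to 65.5 and 57.6. It was lower in T-lineage cells too, by -3.33 to -2.67 over the alternatives without the block. Free RNA as a source of the Fcer2a difference was not tested. Serpinb6b (a protease inhibitor gene) fell by 2.54 (adjusted p = 1.78e-05), and log2 differences were -2.51 for Slpi (a secreted protease inhibitor gene) and -1.91 and -2.36 for Snhg9 and Tsix, both noncoding RNAs. Tsix overlaps Xist on the opposite strand, so its counts are uncertain. Hspa1a and Hspa1b are near-identical copies, so reads can be split between them. Cdk8 fell by 3.70, but its level was 2042 CPM in SFB-negative replicate 2 against 26.4 in SFB-negative replicate 1 and 18.6 and 65.1 in the SFB-positive libraries. Without that library its log2 difference was 0.71. Cdk14 (1.95), Arhgap39 (1.66), Pkp4 (1.46) and Slc15a2 (1.46) rose, and without SFB-positive replicate 2 their log2 differences turned to -0.93, -0.10, -0.28 and -0.26. Hist1h4d fell by 3.40, and was 2.19 higher without SFB-negative replicate 2. The other genes named by the rule were Luzp1 (1.55), which rose, and Pet100 (-1.59), Smim27 (-1.59), Hist2h2aa1 (-1.66) and Hbb-bt (-1.68), which fell. Hbb-bt is a haemoglobin gene and marks red-cell RNA. Among 9876 genes tested in cluster 3, edgeR with the replicate block called 37 higher and 96 lower. Of these, 27 of 72 histone genes and 24 of 610 unnamed gene models were lower, against 0 and 1 higher. Of the 88 lower genes at 10 CPM or more in the higher group, 81 had their highest level in SFB-negative replicate 2.

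In cluster 3 several gene lists passed by camera with its preset correlation, and none with an estimated correlation. The heat shock list was higher (camera adjusted p = 0.00288, and 6.84e-05 with the replicate block), with 3 of 12 genes higher, Hspa1b (2.63), Hspa1a and Hsph1 (1.17). The naive follicular B-cell list was lower (camera adjusted p = 0.00764 and 0.0106), with Fcer2a the gene past the limit, of 16. By the same test that list was lower in T-lineage cells as well, and free RNA was not tested for it. The MHC class II list (genes that present peptides to CD4 T cells; 0.0101 and 0.0101) and the oxidative phosphorylation list (0.00288 and 0.0106) were lower with 0 of 14 and 0 of 22 genes past the limit over all genes, and 0 and 1 (Cox7c) adjusted over the list alone. The type I interferon list was lower without the block (0.0426) and not with it (0.103), with Ifi27l2a (-1.24) past the limit. With an estimated correlation, each of these camera calls had an adjusted p = 0.615. Without SFB-positive replicate 2 the adjusted p of the MHC class II list became 0.897 and that of oxidative phosphorylation 0.952. Lists of germinal-centre (0.775), class-switch (0.0853), cell-cycle (0.181), plasma-cell (0.786), memory (0.444), atypical memory (0.444), activation (0.775), interferon-gamma (0.775), Th17 (0.766), Tfh (0.240), naive T (0.170), glycolysis (0.240), migration (0.160) and immediate-early genes (0.775) did not pass by camera adjusted p with the block. The mitochondrial list passed with the block alone (0.0106 against 0.180), with mt-Atp8 (-2.24), mt-Nd3 (-1.53) and mt-Nd6 (-1.25) lower, and not with an estimated correlation (0.796 with the block).

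Memory-like B cells (cluster 4; led by Fcrl5, Plac8 and Ccr6) had more Ighg2b and less Ighg1 in SFB-positive libraries. The name is weakly held, at a score of 0.962. Its 10 leading genes hold 1 memory marker (Ccr6) and 1 marker of marginal-zone or innate-like B cells (Fcrl5). Ighg2b took 1.82% ± 0.801 (SD, n = 2) of their heavy-chain constant UMIs in SFB-negative and 6.74% ± 1.07 in SFB-positive libraries, and the shares differed by 4.73 and 5.10 points within the replicate numbers. Igha took 13.3% ± 0.391 and 10.1% ± 1.82, Ighm 73.2% and 70.6%, and Ighg1 1.40% and 0.289%. The exact two-sided p was 0.333 for Ighg2b, Igha and Ighg1 and 0.667 for Ighm. Ighg2b rose 4.43-fold (log2 2.15 ± 0.30, SE, adjusted p = 1.09e-09), and Ighg1 fell by 1.94 ± 0.38 (adjusted p = 1.44e-04). Ighg3 (the IgG3 heavy chain) rose by 1.73 (adjusted p = 2.79e-04; 1.27 to 9.77 over the alternatives without the block), but 1 cell carried much of it: without the cell of most constant UMIs its share in SFB-positive replicate 2 went from 2.87% to 0.963%, and the difference within number 2 from 1.56 to -0.365 points. Igha did not pass (log2 -0.16, adjusted p = 0.908), and without SFB-negative replicate 1 its difference turned to 0.85. Among 8500 genes, 24 were higher, Pitpnc1 (1.59) with them, and 106 lower, including Hes1 (a Notch target, -1.97) and Ndufa5 (a respiratory-chain gene, -1.84). Without the block the adjusted p of Ighg2b ranged from 0.590 to 1.00 over the alternatives.

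The Igha difference depended on the class: it was smaller in cluster 4 than in cluster 3 by 2.31 on the log2 scale (interaction, edgeR adjusted p = 1.13e-13). The Ighg2b difference (-0.51, adjusted p = 1) and the Ighg1 difference (0.63, adjusted p = 1) between these clusters did not pass. The interaction called 6 of 9651 genes, with 353 at an unadjusted p under 0.05.

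Plasma-like cells (cluster 6; led by Jchain, Prg2 and Slpi), the antibody-secreting class, numbered 6, 30, 24 and 68 in the libraries, too few for a gene test. Ighg2b took 0%, 7.14%, 28.0% and 51.8% of their heavy-chain constant UMIs, with exact upper bounds of 0.0409% and 7.54% in the SFB-negative libraries. The group means were 3.57% ± 5.05 (SD, n = 2) and 39.9% ± 16.8, with an exact two-sided p of 0.333. The Ighg2b count of 0 comes from 6 cells, and 1 cell held 1133 of the 1221 Ighg2b UMIs of SFB-negative replicate 2, so the bounds, which count UMIs, are narrower than the spread between cells. Igha took 70.4% ± 31.0 and 44.6% ± 20.5 of the UMIs (exact p = 0.667), but by dominant gene the direction reversed, with 31.7% and 36.9% Igha cells.

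Over all B-lineage cells, Ighg2b, Prg2, Jchain and Igha were higher with SFB. Ighg2b rose 33.8-fold (log2 5.08 ± 0.40, SE, n = 2 per group, adjusted p = 9.74e-33), with log2 differences of 5.50 and 4.68 within the replicate numbers. Plasma-like cells, 24 of 3408 and 68 of 7380 table cells, held 8379 of 10307 and 88767 of 96585 of the Ighg2b UMIs in SFB-positive replicates 1 and 2, so this fold and the share below also follow the number of these cells. Prg2, a granule protein gene that leads the plasma-like cluster (ENSMUSG00000027073, chromosome 2, plus strand, 84980461 to 84983632), rose 11.1-fold (log2 3.47 ± 0.27, adjusted p = 1.39e-33), from 0.862 and 2.27 to 30.3 and 17.3 CPM. Jchain, which joins IgA and IgM units, rose 2.65-fold (adjusted p = 0.00354) and Igha 2.58-fold (log2 1.37 ± 0.38, adjusted p = 0.0145), though the Igha difference was -0.04 without SFB-positive replicate 1. Ighg3 rose 5.83-fold (adjusted p = 7.78e-16), by 0.40 within number 1 and 3.35 within number 2, and its difference was -0.52 without SFB-positive replicate 2. Ighg1 (-0.25, adjusted p = 0.866), Ighd (-0.12, 0.966) and Ighm (0.23, 0.938) did not pass. Of heavy-chain constant UMIs, Ighg2b took 1.92% ± 1.75 (SD) and 27.0% ± 11.6, Igha 22.0% ± 5.46 and 29.3% ± 7.82, Ighm 53.3% ± 5.78 and 32.3% ± 6.16, Ighd 15.8% and 7.42%, Ighg1 6.40% and 2.21%, and Ighg3 0.433% and 1.78%. Single cells weigh on these shares: without the cell of most constant UMIs in each library Igha took 12.9% and 25.6%, and its share in SFB-negative replicate 1 went from 25.9% to 12.4%. By dominant gene Ighm reversed, with 80.1% and 82.4% Ighm cells. Rsph1 (1.80), Hspb1 (a small heat-shock gene, 1.49), Iglc1 (a light-chain constant gene, 1.42), Lefty1 (1.15) and Slc15a2 (a peptide transporter gene, 1.35) also rose. Cdk14 (1.95), Osbpl3 (1.51) and Tox (1.46) rose too, but without SFB-positive replicate 2 their differences were -1.45, -0.51 and -1.36. Without the block the adjusted p of Ighg2b ranged from 2.40e-17 to 1.00 over the alternatives, and that of Prg2 from 0.0234 to 1.00.

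Ighg2b was also higher in classes that do not secrete antibody. It rose in naive-like clusters 0 (log2 3.51, adjusted p = 9.35e-28) and 1 (4.02, 8.82e-08) and in cluster 2 (4.22, 3.18e-23). It rose likewise in T-lineage cells, which do not transcribe antibody genes, from 0 and 1.10 CPM to 158 and 16.5. These values include free RNA in the droplets. In CPM of the raw class totals, Ighg2b stood at 79.4 and 30.5 in clusters 0 to 2 of SFB-positive replicates 1 and 2, against 151 and 18.4 in T-lineage cells and 1541 and 382 in cluster 3. Of the 71 Ighg2b UMIs in T-lineage cells of SFB-positive replicate 1, 48 lay in 1 cell, without which the rate was 49.0 CPM. Without the block the adjusted p of Ighg2b ranged from 0.0970, 0.0988 and 0.00193 to 1.00 in clusters 0, 1 and 2.

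**Figure D2:**
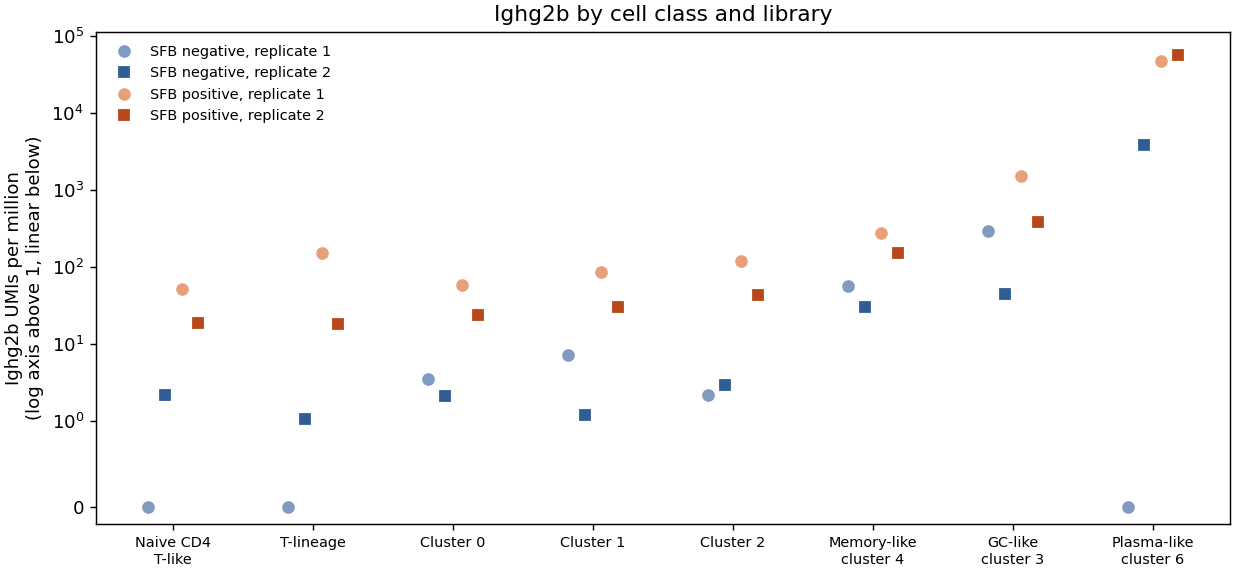
Ighg2b CPM of raw class totals (vertical axis, log scale above 1 and linear below) by cell class, with 1 point per library. Both SFB-positive libraries lie above both SFB-negative libraries in each class drawn, T cells included.

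Among 12268 genes in all B-lineage cells, edgeR with the block called 114 higher and 329 lower. Of the 158 lower genes at 10 CPM or more in the higher group, 132 had their highest level in SFB-negative replicate 2. The lower genes included 30 of 89 histone genes, 147 of 1342 unnamed gene models, 9 of 62 antibody variable segments, 3 of 13 mitochondrial transcripts and 2 of 98 ribosomal protein genes. Snhg9 fell by 1.95, Tsix by 1.93, Smim27 by 1.44, Hcst (a signalling adaptor gene) by 1.32 and AL590144.2 by 1.30 on the log2 scale, and Pet100 (a respiratory-chain assembly gene) went to 0.435 of its level. AY036118 fell by 3.90, Hist1h4h by 3.01, Hist1h3e by 2.85 and Hist2h2ac by 1.38, with their highest levels in SFB-negative replicate 2. Without that library their differences were 2.59, 1.00, 2.42 and 2.46. Ube2v1 (-1.61) and Rab26os (-1.21) turned to 0.43 and 0.24 without SFB-negative replicate 1. In the other B-cell classes the rule also named Hspa1b (1.64) and Slc15a2 (1.53), higher in cluster 0, AY036118 (-4.13), Hist1h4h (-3.73) and Tsix (-2.02), lower there, and Ighg1 (-2.23, adjusted p = 7.70e-06). The Ighg1 share of heavy-chain constant UMIs in cluster 0 differed by 0.0121 points within number 1 and -0.981 within number 2. In T-lineage cells it differed by 0.727 and -6.84 points, and free RNA was not tested for Ighg1. In cluster 1 Slc15a2 (1.59) and Socs3 (a cytokine-signal inhibitor gene, 1.37) were higher and Hist1h4d (-3.66), Mfsd4a (-2.45) and Tsix (-2.14) lower. In cluster 2 Hspa1a (1.79) and Hspa1b (1.76) were higher and Lars2 (-3.60), Cmss1 (-2.78) and Mfsd4a (-2.76) lower. Leaving out SFB-negative replicate 2 gave positive differences for AY036118 (2.86) and Hist1h4h (0.73) in cluster 0, Hist1h4d (2.58) in cluster 1, and Lars2 (1.54) and Cmss1 (2.31) in cluster 2. Without SFB-positive replicate 2 that of Hspa1b in cluster 2 was -1.05.

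Across all B-lineage cells, lists of cell-cycle, heat-shock, germinal-centre and plasma-cell genes were higher in SFB-positive libraries by camera with its preset correlation, and not with an estimated one (adjusted p = 0.596 for the first 3 and 0.735 for plasma cells). The class make-up can carry the differences of the cell-cycle, germinal-centre and plasma-cell lists. With the block, cluster 3 took a 1.37-fold (edgeR adjusted p = 0.0488) and plasma-like cells a 2.82-fold (0.0176) share of table cells, and within cluster 3 the cell-cycle and germinal-centre lists did not pass. Without the block neither share of table cells passed (edgeR adjusted p = 0.820 and 0.525). As a share of annotated cells, cluster 3 did not pass with the block either (edgeR adjusted p = 0.100), so its part in the make-up is uncertain. The heat shock list was higher within clusters 0, 1, 2 and 3 as well. Camera with the preset correlation and no block gave adjusted p = 4.81e-07, 2.24e-05, 2.78e-08 and 0.00288 there, and 0.291 in cluster 4. With an estimated correlation and no block, camera gave adjusted p = 0.663, 0.797, 0.473 and 0.615 in clusters 0 to 3. These calls rest on the preset correlation, and heat-shock genes lead cluster 1, so they cannot exclude class make-up as the source. For the cell-cycle list, camera gave an adjusted p = 1.07e-10 (3.50e-09 with the block), and 4 of 28 genes rose, Mki67 (1.02), Cenpf (0.94), Cenpe (0.76) and Rrm2 (0.74), and 9 adjusted over the list alone. For heat shock it gave 1.64e-06 (8.76e-06), with Hspb1, Hspa1a (2.30-fold) and Hspa1b (1.07) higher and 5 of 12 adjusted over the list alone. For the germinal-centre programme it gave 0.00130 (0.00137), with Lipc (0.78) and Mybl1 (0.92) higher and 7 of 22 adjusted over the list alone. For the plasma-cell programme it gave 0.0133 (0.0105), with Jchain and Derl3 (0.71) higher and 3 of 24 adjusted over the list alone. Without SFB-negative replicate 2 the plasma-cell value was 0.538. The type I interferon list was lower (3.59e-05, and 0.0105 with the block, estimated-correlation p = 0.704), with Ifi27l2a (-1.08) past the limit, lost the call without SFB-negative replicate 1 (0.410) and turned higher without SFB-positive replicate 2. Oxidative phosphorylation was lower without the block alone (0.0163 against 0.180), with 0 of 22 genes past the limit, and 0.775 without SFB-negative replicate 1.

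Markers of other tissues moved with the groups too. The epithelial contaminant list was lower in SFB-positive B-lineage cells (camera adjusted p = 4.95e-09, and 0.0163 with the block, estimated-correlation p = 0.614), with Defa24 (-3.97), Fabp2 (-3.47) and Epcam (-0.95) past the limit. Its median without the block was positive, opposite to the test, and the list turned higher without SFB-positive replicate 2. The myeloid contaminant list was lower without the block (0.0133) and not with it (0.103), with Lyz2 (-1.49) past the limit and an estimated-correlation p = 0.663. Stromal and erythroid contaminant lists had too few tested genes. The mitochondrial list was lower with the block alone (0.0105 against 0.107), and not with an estimated correlation (0.896 with the block).

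The atypical memory list, genes of T-bet+ CD11c+ B cells, did not pass in all B-lineage cells (camera adjusted p = 0.763, and 0.797 with the block). Of its 22 tested genes Itgax, the CD11c gene (2.29, adjusted p = 0.0201), Zeb2 (0.81, 0.0282) and Sox5 (0.85, 0.0458) rose, and adjusted over the list alone these 3 rose and Nkg7 fell. Tbx21, the T-bet gene, did not pass (1.03). Neither did the lists of class-switch (0.0840 with the block; Batf rose by 0.71), memory (0.242; Nt5e by 1.17), naive follicular (0.474), activation (0.765), MHC class II (0.180), interferon-gamma (0.310), Th17 (0.236; Il1r1 rose by 1.12, Il22 fell by 1.62), Tfh (0.546; Tox and Tox2 rose), Treg (0.604), naive T (0.310), cytotoxic (0.746), glycolysis (0.442; Hk2 fell by 0.96), migration (0.841) or immediate-early genes (0.639; Jun rose by 0.97 and Socs3 by 1.06).

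T-lineage cells of SFB-positive libraries expressed more type 3 cytokine genes, of which Il17a and Il17f were nearly undetected in SFB-negative libraries. Il17a, the IL-17A cytokine gene (ENSMUSG00000025929, chromosome 1, plus strand, 20730905 to 20734496), had 1 UMI over both SFB-negative and 925 over both SFB-positive libraries. Its pooled rate was 429 times higher (exact 95% counting interval 76.8 to 16969), at 0 and 0.275 against 386 and 77.1 CPM (adjusted p = 1.43e-15). Il17f (ENSMUSG00000041872, chromosome 1, minus strand, 20777146 to 20790617) had 0 against 177 UMIs and was at least 27.4-fold higher, against a floor of 3 counts over the group (adjusted p = 5.18e-07). Il22, an epithelial-defence cytokine gene (ENSMUSG00000074695, chromosome 10, plus strand, 118204942 to 118210047), rose 8.45-fold (log2 3.08 ± 0.25, SE, n = 2 per group, adjusted p = 4.52e-11), by 3.12 and 3.02 within the replicate numbers. Il23r, the IL-23 receptor gene (ENSMUSG00000049093, chromosome 6, minus strand, 67422932 to 67491855), rose 17.4-fold (log2 4.12 ± 0.46, adjusted p = 7.56e-08). ILC3-like cells, also led by Il22 and Il23r, were kept out of the T lineage by a limit set after the data were examined. They numbered 46 and 136 in SFB-negative and 16 and 60 in SFB-positive libraries. The Il22 and Il23r differences with these cells included were not tested. Lag3, an inhibitory receptor gene, rose by 2.10 ± 0.27 on the log2 scale (adjusted p = 1.50e-06). Without the block the adjusted p over the alternatives ranged from 5.16e-09 to 1.00 for Il17a, from 0.00153 to 1.00 for Il17f, from 0.163 to 1.00 for Il22 and from 0.293 to 1.00 for Il23r, and the log2 difference from 1.80 to 6.91 for Il22 and from 3.51 to 9.63 for Il23r.

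**Figure D3:**
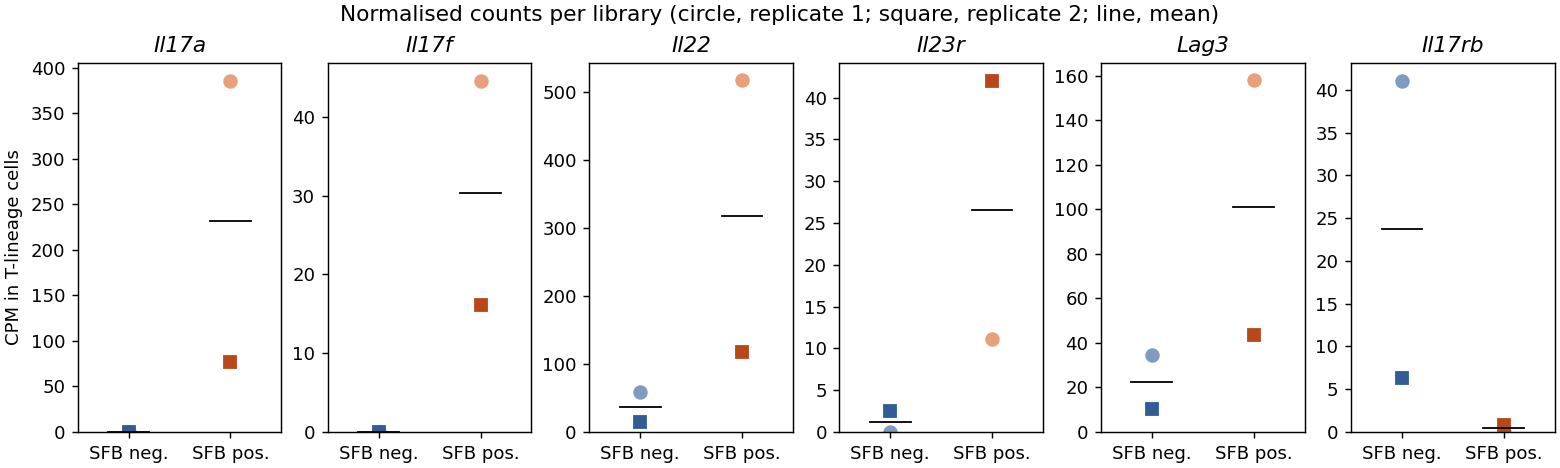
CPM (vertical axes, linear, a scale of its own per gene) of Il17a, Il17f, Il22, Il23r, Lag3 and Il17rb in T-lineage cells, with 1 point per library (circle, replicate 1, square, replicate 2) and a line at the group mean. Il17a and Il17f lie at or near 0 in both SFB-negative libraries, whose points overlap, and between 16.1 and 386 CPM in the SFB-positive libraries.

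Among 9371 genes in T-lineage cells edgeR with the block called 70 higher and 162 lower. The higher genes included Il1r2 (a decoy IL-1 receptor gene, 1.73), Zeb2 (1.74), Igf1r (1.65), Nebl (1.71), Cysltr1 (1.75), Cdk5r1 (1.76) and Fam20a (1.82). Without SFB-positive replicate 2 the Igf1r difference was -1.31. The lower genes included Il17rb (-3.40), Hs3st1 (-3.38) and Calca (-2.64), which lead a small unnamed cluster of 7, 8, 0 and 2 cells. Xcl1 (a chemokine gene, -2.43), Tyrobp (an NK and myeloid adaptor gene, -2.25), Klra7 (-2.53), Klrg1 (-2.53) and Fgl2 (-2.22) fell, as did Tsix (-3.15). Ccl1, a chemokine gene, had 33 against 1 UMIs, a rate 71.1 times higher in SFB-negative libraries (exact 95% counting interval 11.9 to 2893). Cmss1 fell by 4.01, but without SFB-negative replicate 2, where it reached 4613 CPM, its difference was 3.16. Of the 148 lower genes at 10 CPM or more in the higher group, 107 had their highest level in that library. B-cell genes were lower in the T-lineage cells of SFB-positive libraries: Fcer2a by -2.77, Ly86 by -2.84, Iglc2 by -2.09 and, in naive CD4 T-like cells, Cd79a by -2.32 (103 and 61.6 against 26.7 and 11.6 CPM) and Ms4a1 by -1.95. Part of the naive CD4 T-like difference can follow the make-up of that class: a low-depth cluster in it, with Cd79a at 112 CPM against 20.7 and 22.7 in the 2 other clusters made up mostly of replicate 2 cells, held 139 of 484 cells in SFB-negative replicate 2 and 18 of 452 in SFB-positive replicate 2, against 0 of 133 and 1 of 117 in the replicate 1 libraries. Histone genes were lower in 16 of 53 and unnamed gene models in 35 of 465.

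The Th17 and type 3 list was higher in T-lineage cells (camera adjusted p = 2.21e-13, and 8.16e-16 with the block, estimated-correlation p = 0.309). Of its 17 genes 10 rose and Csf2 fell (-3.43), and adjusted over the list alone 12 rose and 1 fell. The Tfh list was higher (0.0111, and 0.00731 with the block, estimated-correlation p = 0.964), with Tnfsf8 (1.45), Icos (0.88) and Maf (0.89) higher and Sostdc1 (-1.54) and Pdcd1 (-0.90) lower, and it lost the call without SFB-positive replicate 2 (0.991). The heat shock list was higher (0.0184 and 0.00176, estimated-correlation p = 0.834), with Hspa1a (1.34) and Hspa1b (1.21) past the limit. The MHC class II list was lower (1.45e-12 and 8.16e-16, estimated-correlation p = 0.661), with 9 of 14 genes lower, among them H2-Eb1 (-1.61), Ciita (-2.33), Cd86 (-2.10) and H2-Ab1 (-1.35), and 12 adjusted over the list alone. These are B-cell genes as well. The naive follicular B list was lower (0.0102 and 0.00528, estimated-correlation p = 0.661), with Fcer2a and Bank1 (-1.72). The cytotoxic list was lower (5.15e-04 and 3.39e-04, estimated-correlation p = 0.910), with Klrg1, Klrd1 (-1.16) and Ctsw (-1.06) past the limit and 7 of 14 adjusted over the list alone. The class includes an NK or ILC1-like cluster, which expresses such genes and held 7 of 290 and 30 of 1046 cells in SFB-negative against 3 of 309 and 18 of 1237 in SFB-positive libraries. Without SFB-positive replicate 2 the MHC class II value was 0.980 and the cytotoxic value 0.991. Oxidative phosphorylation passed with the block alone (0.00725 against 0.0713, and 0.864 with the block and an estimated correlation), with Atp5e (-0.96) and Cox6c (-0.89) lower. Lists that did not pass with the block were those of Treg (0.784; Ctla4 rose by 1.51), plasma (0.0812; Mzb1 fell by 2.29), memory (0.827), atypical memory (0.0705), cell-cycle (0.754; Mki67 rose by 1.23), type I interferon (0.335; Ly6a rose by 0.98), mitochondrial (0.148), germinal-centre (0.784), class-switch (0.559), activation (0.784), interferon-gamma (0.689), naive T (0.856), glycolysis (0.0705), migration (0.784) and immediate-early genes (0.559).

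In the T-cell classes with enough cells, naive CD4 T-like cells had 9 higher and 88 lower genes with the block, and CD8 T-like cells 5 and 24. In naive CD4 T-like cells Elovl6 (a fatty-acid elongase gene, 1.40) and Hspa1a (1.39) rose. In CD8 T-like cells Ccl4 (a chemokine gene, 2.47) and Elovl6 (1.70) rose, and Capn3 (-3.61), Tyrobp (-3.09) and H2-DMb2 (-2.12) fell. The CD8 T-like class includes a cluster led by Gzma, Ccl5, Gzmb and Trdc, which held 18 of 124 and 47 of 294 of its cells in SFB-negative against 6 of 103 and 33 of 353 in SFB-positive libraries, so its lower genes can follow this make-up. The Elovl6 difference in CD8 T-like cells was -0.36 without SFB-positive replicate 2. Ighg2b had 1 against 103 UMIs there, a rate 55.3 times higher (exact 95% counting interval 9.71 to 2206), in cells that do not make antibody.

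Th17-like cells, IL-17-producing T cells that SFB are known to induce, made up 0%, 0.0863%, 0.988% and 0.797% of annotated cells in SFB-negative replicates 1 and 2 and SFB-positive replicates 1 and 2. Of 4398 cells 0 were Th17-like in the first, which allows a share of up to 0.0682% (3 counts; the exact two-sided 95% interval reaches 0.0838%). With the block the share rose 14.4-fold (edgeR adjusted p = 7.50e-05). This class is recognised by Il17a, Il22 and Il23r, so its size is not separate evidence from those genes. Tfh-like cells, T cells that help germinal-centre B cells, rose 2.42-fold (0.815% ± 0.831 and 1.99% ± 1.30, SD, n = 2, edgeR adjusted p = 0.00450), but as a share of T-lineage cells did not pass (2.10-fold, adjusted p = 0.146). Plasma-like cells rose 2.79-fold (0.230% ± 0.132 and 0.702% ± 0.0866, edgeR adjusted p = 0.0107). ILC3-like cells fell to 0.445 of their share (1.26% ± 0.298 and 0.550% ± 0.174, edgeR adjusted p = 0.0107). Memory-like cells (3.43% ± 0.859 and 4.82% ± 1.07, adjusted p = 0.0875) and germinal-centre-like cells (5.56% ± 3.104 and 7.37% ± 2.76, adjusted p = 0.100) did not pass, nor did T-lineage cells as a whole (8.94% and 11.1%, 0.224). With cluster 5 and deep germinal-centre-like barcodes from outside the table added, the germinal-centre-like share was 7.60% and 9.59% (adjusted p = 0.127). Naive-like clusters 0 and 1 are compared combined, because the heat-shock genes that lead cluster 1 differ between the groups and can move cells from one cluster to the other. Whether cells moved in this way was not tested. Combined they took 67.1% ± 9.55 and 62.9% ± 9.88, and Treg-like (0.468% and 0.404%), naive CD4 T-like (4.12% and 4.10%) and CD8 T-like cells (2.995% and 3.36%) differed by less than their spread. As a share of T-lineage cells, naive CD4 T-like cells took 46.1% ± 0.290 and 37.2% ± 0.936 without overlap (log2 -0.28 and -0.34 within the replicate numbers), which did not pass (edgeR adjusted p = 0.493, and 0.182 without the block). The difference within number 2 can follow the low-depth cluster of this class. That cluster held 139 of 484 cells in SFB-negative and 18 of 452 in SFB-positive replicate 2. Lef1, Grap2, Neto2, Fgf13, Atp8b4 and Sidt1 lead it and also a CD8 T-like cluster, so its name is uncertain. The share without that cluster was not tested. Without the block no class passed: the edgeR adjusted p was 0.199 for Th17-like, 0.892 for Tfh-like, 0.403 for plasma-like and 0.452 for ILC3-like cells. The sort for CD45 and the number of cells loaded set the pool these shares are taken from. Annotated cells leave out the B-like barcodes set aside outside the table, so shares of annotated cells depend on that choice.

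**Figure D4:**
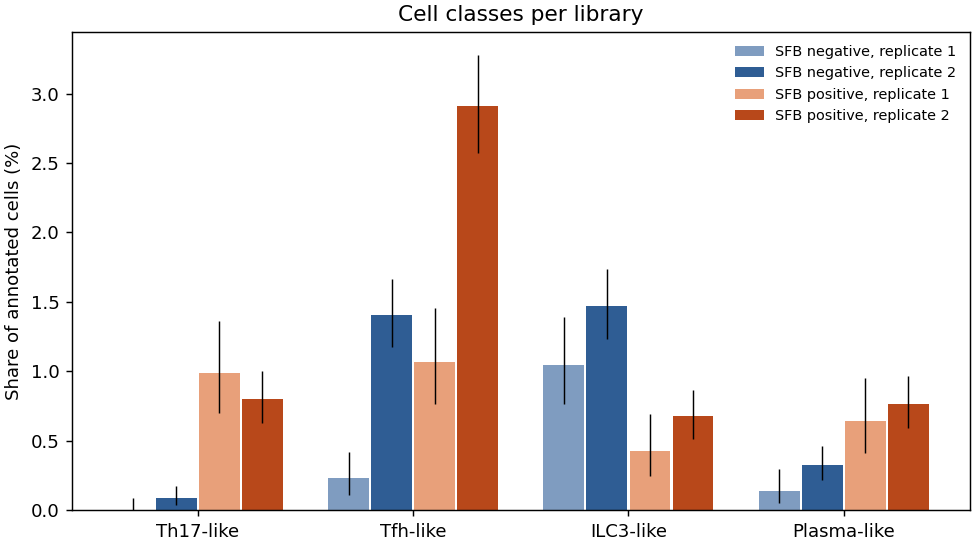
Share of annotated cells (percent, vertical axis) of 4 classes, with 1 bar per library and its exact 95% binomial interval, which covers counting error only. Th17-like and plasma-like shares stand higher and ILC3-like shares lower in both SFB-positive libraries, whereas Tfh-like shares of the groups overlap.

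Without the replicate block, edgeR called 0 genes in each of the 9 classes. At an unadjusted p under 0.05 it counted 12 genes in all B-lineage cells, 7, 7, 12, 12 and 16 in clusters 0 to 4, 38 in T-lineage, 10 in naive CD4 T-like and 13 in CD8 T-like cells. DESeq2 without the block called 2 genes in all B-lineage cells (Ighg2b and Prg2), 1 in cluster 2 (Ighg2b), 2 in T-lineage cells (Il17a and Ighg2b) and 0 in the other classes. With the block edgeR called 443, 229, 98, 102, 133, 130, 232, 97 and 29 genes in the same order, and DESeq2 22, 5, 7, 5, 5, 4, 10, 3 and 2. The common biological coefficient of variation was 0.644 in all B-lineage cells without the block and 0.161 with it. Genes called with the block and at 10 CPM or more in the higher group numbered 237, 125 and 215 in all B-lineage, cluster 3 and T-lineage cells. Of these, 79.3%, 88.0% and 77.2% had the same sign within both replicate numbers, against 50.4%, 49.3% and 53.2% of all genes at that level. Under 10 UMIs over the replicate 1 libraries were held by 37, 58 and 69 of them, so their sign there rests on few UMIs. In cluster 1 the same-sign share was 54.9% (51.0% of all genes), in naive CD4 T-like cells 62.5%, in cluster 2 66.0%, in cluster 0 67.4%, in CD8 T-like cells 79.3% and in cluster 4 83.6%. The model with the block favours genes that agree, so these values are not separate evidence.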

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

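The test of a difference between clusters 3 and 4 was chosen only after the data were seen, and the same test of each of them against cluster 0 was run and left out. It asked, gene by gene, whether the SFB effect differed between germinal-centre-like cells (cluster 3) and memory-like cells (cluster 4). The edgeR interaction test, with the library as a block, called 6 of 9651 genes, each of which is given here because its effects in the clusters differ. Values are the effect in cluster 4 minus that in cluster 3, on the log2 scale.

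Igha, the IgA heavy chain, had the smallest adjusted p of the 6, with a difference of -2.31 (adjusted p = 1.13e-13). It rose by 2.20 in germinal-centre-like cells and did not pass in memory-like cells (-0.16). Serpinb6b, a protease inhibitor gene, differed by 2.80 (adjusted p = 0.00331), with effects of -2.54 and 0.14 in clusters 3 and 4. Tanc2, a scaffold protein gene, differed by 2.44 (adjusted p = 3.77e-04), with effects of -2.31 and -0.03. Gsn, which encodes the actin-severing protein gelsolin, differed by 1.29 (adjusted p = 0.0117), with effects of -0.50 and 0.70. The germinal-centre genes Nuggc and Mybl1 differed by -4.14 (adjusted p = 6.20e-04) and -2.59 (adjusted p = 0.0382). Their effects in cluster 3 were 0.25 and 0.62, and both were too low in cluster 4 to be tested there alone. No technical or biological explanation was tested for these 6 differences.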

How the results depend on the processing

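The combinations with the replicate block, the top-score doublet threshold, the wider germinal-centre share, clusters 0 and 1 combined and isotype shares without the highest cell were chosen only after the data were seen. The other alternatives were fixed before. Cell shares, genes and gene lists were compared with the model without the block, in which no cell class and no gene passed. For cell shares and named genes, a kept side of the limit therefore means that the result still did not pass. Over the alternatives, cell shares kept their direction and side of the limit in 81 comparisons, reversed in 15 and gained the limit in 13. Named genes did so in 1081, 44 and 134. Isotype shares kept their direction in 159 and reversed in 9. Gene lists kept theirs in 66, reversed in 15, gained the limit in 8 and lost it in 107. Counts of genes stayed at the first count, which was 0 in each class, in 66 and moved in 87 comparisons. Unless a reason is given, the cause was not tested.

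The labels do not say that replicate numbers pair the libraries, and 2 pairs are too few to show it. Libraries with the same number deviated together from their group means (correlation across genes from 0.722 in CD8 T-like cells to 0.926 in all B-lineage cells). With 2 libraries per group, the correlation of the crossed pairs is the same value with the opposite sign by construction. Libraries with the same number also shared 30 and 40 cell barcodes, against at most 1 between other libraries. Both can come from the technical batch that the number marks, and neither shows that pools of mice are paired. With the number as a block, edgeR called 443 genes in all B-lineage cells instead of 0, 229, 98, 102, 133 and 130 in clusters 0 to 4, 232 in T-lineage, 97 in naive CD4 T-like and 29 in CD8 T-like cells. The block reversed Ighm in cluster 3 (0.16). The common coefficient of variation dropped to 0.161, 0.185 and 0.149 in all B-lineage, cluster 3 and T-lineage cells, from 0.644, 0.558 and 0.585. Simulated data with a built-in replicate effect recovered 0% of 8-fold changes without the block and 100% with it in these 3 classes. As that effect was set in advance, they do not show that the block suits the real data.

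In the same order of 9 classes, the block gave 22, 5, 7, 5, 5, 4, 10, 3 and 2 genes with DESeq2. With cells thinned to 1000 UMIs it gave 180, 78, 69, 23, 29, 6, 54, 21 and 20, from fewer UMIs. With no low-count filter it gave 332, 199, 188, 93, 135, 134, 291, 81 and 84, and with median-of-ratios scaling 260, 195, 129, 90, 141, 119, 277, 35 and 68. With that scaling 36 genes rose and 83 fell in cluster 4, against 24 and 106 with TMM. Without immunoglobulin genes it gave 432, 224, 102, 102, 128, 126, 184, 95 and 37, and without high-scoring doublets 427, 219, 193, 100, 116, 121, 276, 91 and 47. Without the block, DESeq2 called 2 genes in all B-lineage cells, 1 in cluster 2 and 2 in T-lineage cells, and gave -0.0031 for Ighg3 in cluster 3. Having no low-count filter called 3, 0, 0, 1, 1, 0, 6, 3 and 5, while thinning, scaling, leaving out immunoglobulin genes and leaving out doublets called 0 in each class.

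Each library was also left out of the model without the block, where the lone library of a group is assumed to vary like the other group. Counts of genes then ran from 0 to 3 in all B-lineage cells and cluster 0, from 0 to 2 in cluster 1, from 0 to 4 in cluster 2, from 0 to 7 in cluster 3 and T-lineage cells, from 0 to 4 in naive CD4 T-like and from 0 to 5 in CD8 T-like cells. The highest counts came without SFB-negative replicate 1. Log2 differences that changed sign are given as ranges. In all B-lineage cells they ran from -0.52 to 4.04 for Ighg3, from -1.45 to 5.59 for Cdk14, from -0.51 to 5.27 for Osbpl3, from -1.36 to 4.98 for Tox, from -0.0395 to 2.86 for Igha, from -8.52 to 2.59 for AY036118, from -4.32 to 1.00 for Hist1h4h, from -6.58 to 2.42 for Hist1h3e, from -3.62 to 0.43 for Ube2v1, from -4.10 to 2.46 for Hist2h2ac, from -2.80 to 0.24 for Rab26os, from -0.68 to 0.23 for Ighg1, from -1.05 to 0.80 for Ighd and from -0.9999 to 1.54 for Ighm. In cluster 0 they ran from -8.83 to 2.86 for AY036118 and from -4.46 to 0.73 for Hist1h4h. In cluster 1 they ran from -6.55 to 2.58 for Hist1h4d. In cluster 2 they ran from -1.05 to 3.24 for Hspa1b, from -5.23 to 1.54 for Lars2 and from -6.36 to 2.31 for Cmss1. In cluster 3 they ran from -5.84 to 0.71 for Cdk8, from -0.93 to 4.35 for Cdk14, from -0.10 to 2.96 for Arhgap39, from -0.28 to 2.17 for Pkp4, from -0.26 to 2.70 for Slc15a2, from -6.50 to 2.19 for Hist1h4d, from -0.96 to 3.20 for Ighg3, from -0.60 to 0.96 for Ighd and from -0.86 to 1.29 for Ighm. In cluster 4 they ran from -1.02 to 0.85 for Igha, from -0.40 to 1.12 for Ighd and from -0.95 to 1.39 for Ighm. In T-lineage cells they ran from -1.31 to 4.23 for Igf1r and from -7.76 to 3.16 for Cmss1. In CD8 T-like cells they ran from -0.36 to 2.31 for Elovl6. Of the named genes, 16 reversed without SFB-negative replicate 2 and 16 without SFB-positive replicate 2, against 5 without each of the other libraries.

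The gene-list calls rested on camera's preset correlation. In all B-lineage, cluster 3 and T-lineage cells 0 lists passed with an estimated correlation or by fry, with or without the block. Of 191 list tests over 9 classes, camera with the preset correlation called 47 (49 with the block), the estimated correlation 0 (lowest adjusted p = 0.309, and 0.623 with the block), and fry 1 (naive T genes, higher in CD8 T-like cells, adjusted p = 0.00461) and 0 with the block (0.0793). Leaving out 1 library gave 2 to 6 lists in cluster 3 and moved the camera adjusted p as follows. In all B-lineage cells it ran from 1.50e-05 to 0.538 for the plasma-cell list, from 1.55e-05 to 0.410 for type I interferon, from 7.63e-05 to 0.775 for oxidative phosphorylation, from 0.0101 to 0.820 for mitochondrial transcripts and from 1.69e-12 to 1.71e-04 for the epithelial list, which turned higher without SFB-positive replicate 2. In cluster 3 it ran from 5.71e-05 to 0.897 for MHC class II, from 6.53e-05 to 0.952 for oxidative phosphorylation and from 5.15e-04 to 0.655 for mitochondrial transcripts. In T-lineage cells it ran from 1.60e-17 to 0.980 for MHC class II, from 2.42e-05 to 0.991 for Tfh, from 8.57e-11 to 0.991 for cytotoxic genes and from 0.00253 to 0.980 for oxidative phosphorylation. In T-lineage cells the highest of these values came without SFB-positive replicate 2.

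Apart from Th17-like cells without SFB-negative replicate 2, cell shares passed the limit only with the block: Th17-like at a log2 difference of 3.85, 4.01 without doublets and 3.59 as a share of T-lineage cells, and Tfh-like at 1.27 and 1.28 without doublets. As a share of T-lineage cells, Tfh-like cells did not pass with the block (1.07, adjusted p = 0.146). Plasma-like and ILC3-like shares passed. Among clusters 2 to 6 as shares of table cells, clusters 3 and 4 (0.45, adjusted p = 0.0488, and 0.50, adjusted p = 0.0480) passed too, though not of annotated cells. Clusters 0 and 1 are compared combined. Apart, cluster 0 took 50.9% and 37.1% and cluster 1 25.4% and 35.0% of table cells in SFB-negative and SFB-positive libraries (edgeR adjusted p = 0.0480 each with the block). As shares of annotated cells they did not pass (0.0553 and 0.0717). With TMM over the classes, cluster 2 turned to -0.24 and CD8 T-like cells to -0.0704. As a share of T-lineage cells CD8 T-like cells gave -0.19, and -0.15 with the block. Leaving out 1 library gave log2 differences from -0.24 to 0.30 for cluster 2, from -0.0723 to 1.13 for cluster 3, from -0.12 to 0.75 for T-lineage, from -0.40 to 0.44 for naive CD4 T-like, from -0.12 to 0.40 for CD8 T-like, from -1.14 to 1.36 for Treg-like and from 3.34 to 8.67 for Th17-like cells. The last value was without SFB-negative replicate 2, which leaves SFB-negative at 0 cells, so it is no measure of size.

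Isotype shares of Ighg2b, Igha and Ighg1 in cluster 3 kept their direction under each alternative run. Within replicate number 1, Ighg3 turned to -0.0149 percentage points in all B-lineage cells and -0.506 in cluster 3, and Ighd in cluster 3 to 0.686. By dominant gene, Ighm in all B-lineage cells turned to 2.30 and Igha in plasma-like cells to 5.22 points. Leaving out 1 library gave -0.371 to 3.07 points for Ighg3 in all B-lineage cells, and -0.253 to 0.465 for Ighg3 and -2.60 to 0.549 for Ighd in cluster 3. Depth limits the rarer classes: plasma-like, Tfh-like, Treg-like and Th17-like cells had under 20 cells in at least 1 library and no gene test.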

Other observations

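Of the tests below, all those of free RNA for Ighg2b, of switched cells in clusters 0, 1 and 2 apart, of handling and depth for the heat shock genes, and of a property of SFB-negative replicate 2 were chosen only after the result, or values of some of its genes within each replicate number, had been seen. The tests of switched cells in clusters 0 to 2 together and of RNA that adds a fixed amount to each droplet were chosen before.

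Antibody tags measured surface proteins in the replicate 1 libraries alone, so they compare 1 library with 1 library and carry no test. In germinal-centre-like cells, 49.3% of SFB-negative cells (exact 95% interval 41.0% to 57.7%, 73 of 148) held surface IgG1 tags above the 3 rat control tags, against 6.90% of SFB-positive cells (3.82% to 11.3%, 14 of 203). Surface IgA was above the controls in 11.5% (6.84% to 17.8%) and 17.2% (12.3% to 23.2%). In memory-like cells the IgG1 values were 4.84% and 0.658%. The median number of tag UMIs per germinal-centre-like cell was 33 and 16, and a lower tag depth lowers such shares. The intervals cover counting error only.

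Cluster 5 of the authors' table, with germinal-centre genes at a low depth, held 1, 258, 0 and 209 cells, so nearly all of it came from the replicate 2 libraries. Naive or follicular B-like barcodes were numerous outside the table. Of their clusters, those with a median of 1634 and 1221 UMIs held 670 and 812 barcodes in SFB-negative replicate 2, against 22 and 34 in SFB-positive replicate 2. Others held 190, 132 and 143 against 153, 237 and 122 in these libraries. Apart from B-like and T-lineage barcodes, cell classes outside the table were small. Macrophage-like cells numbered 6 and 44 in the SFB-negative and 4 and 47 in the SFB-positive libraries, cDC1-like cells (a cross-presenting dendritic class) 1, 15, 3 and 9, pDC-like cells (plasmacytoid dendritic cells) 3, 11, 1 and 7, and NK or ILC1-like cells 7, 30, 3 and 18. Epithelial-like cells numbered 2, 99, 3 and 14, with most in SFB-negative replicate 2, although the sort was for CD45+ cells.

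Ighg2b was higher in SFB-positive libraries in naive-like clusters 0 and 1, in cluster 2 and in germinal-centre-like and memory-like cells. In clusters 3 and 4 of the SFB-positive libraries, cells with 3 or more Ighg2b UMIs outnumbered those expected if each cell drew Ighg2b at the higher of the T-lineage and naive CD4 T-like rates. In replicate 1 they numbered 7.99 times (exact 95% interval 6.26 to 10.0) those expected in cluster 3 and 8.39 times (4.80 to 13.6) in cluster 4, and in replicate 2 59.9 times (53.7 to 66.5) and 65.7 times (52.2 to 81.7), which argues against free RNA as the whole source there. The rate itself decides less for cluster 4: it was 5.37 and 8.23 times that of naive CD4 T-like cells but 1.84 and 8.39 times that of T-lineage cells, whose rate in SFB-positive replicate 1 came mostly from 1 cell. For cluster 3 the ratios to T-lineage cells were 10.2 and 20.8, or 4.91 and 20.5 without the cell of most Ighg2b UMIs of cluster 3 in each library. Over clusters 0 to 2 together the rate was at most 1.66 times that of T-lineage cells (0.527 and 1.66 in SFB-positive replicates 1 and 2), and up to 32.4% of Ighg2b UMIs lay in cells with 3 or more of them, but the clusters differ. The T-lineage rate of replicate 1, set mostly by that 1 cell, exceeds the rate of each of these clusters. With it, cells with 3 or more UMIs numbered 1.44 times (0.718 to 2.57) those expected in replicate 1, so the tests that follow use the upper exact bound of the naive CD4 T-like rate. In cluster 2, cells with 3 or more UMIs then numbered 9.10 times (3.93 to 17.9) and 9.02 times (5.34 to 14.3) those expected in replicates 1 and 2, and 5.67 times (2.45 to 11.2) and 2.13 times (1.26 to 3.37) those expected at the rate of cluster 2 itself, which argues against free RNA as the whole source there. They held 54.5% and 54.4% of its Ighg2b UMIs, so a few switched cells may be the source of much of it, and doublets with such cells were not tested. In clusters 0 and 1 free RNA may be the source of most UMIs, as their rates were 1.19 and 1.74 times that of T-lineage cells without the highest T cell in replicate 1, and 1.34 and 1.68 times in replicate 2. Free RNA as the whole source and a contribution of other cells cannot be told apart there, because the ratio to the expected number was 1.72 (0.355 to 5.03) in replicate 1, from 3 cells, and 5.47 (3.39 to 8.36) in replicate 2. A few switched cells stay open in both: cells with 3 or more UMIs held at most 12.2% of the Ighg2b UMIs in cluster 0 and 32.5% in cluster 1, but these were 1 and 7 cells in cluster 0 and 2 and 14 in cluster 1. A response of germinal-centre-like and memory-like B cells to SFB remains an open hypothesis, since the replicate 1 and 2 libraries differ in batch and the pools of mice are unclear.

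The heat shock list was higher in SFB-positive libraries in B-lineage and T-lineage cells by camera with its preset correlation only. With an estimated correlation the adjusted p was 0.596 and 0.834, and by fry 0.983 and 0.991, so the pattern itself is uncertain. Within replicate number 1, where depths are alike, the mean log2 difference in all B-lineage cells was 0.396, with 11 of 12 genes above 0. That argues against the depth of SFB-positive replicate 2 as the whole cause, but it rests on 1 library against 1. Depth stays open as a source of the difference within number 2. Handling during dissociation and sorting may explain the pattern, as T-lineage cells moved the same way, by 0.327 and 0.463 within the replicate numbers. A response of both lineages to SFB would give the same values and was not tested.

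Most genes called with the block in all B-lineage cells were lower in SFB-positive libraries (329 of 443). They held 0.481% and 6.62% of table UMIs in SFB-negative replicates 1 and 2, and 0.361% and 0.986% in SFB-positive replicates 1 and 2, so a property of SFB-negative replicate 2 may account for much of the pattern. Over the 176 of these genes with enough UMIs in replicate 1, the median difference was -0.43 within number 1 and -1.50 within number 2, a ratio of 0.286. A property of that library and a difference in both replicate numbers cannot be told apart by this ratio, because the genes were chosen by a model that favours agreement between the numbers, which raises it. RNA that adds a fixed amount to each droplet would weigh more in shallow cells, but the share of these genes in the shallower cells of cluster 0 was 1.18 times that in the deeper ones (8.26% and 7.02%), which argues against it as the main source. A biological cause was not tested.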
